A study of Mus musculus with 4 samples.

How the data were processed

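Expression was measured on Affymetrix mouse arrays in RNA from aortas of 6-week-old mice, 2 arrays per genotype (Smad4-KO and WT littermates). Per the labels, each array took 400 ng of RNA from a pool of 3 to 5 vessels, and the arrays of a genotype are biological replicates, so the p-values rest on the spread between pools. The deposited values are probe set intensity on a linear scale. Per the submitters' processing notes, Affymetrix Expression Console and RMA were used, with no version given. The values do not have the form RMA gives: they are not on a log scale, their distributions differ between arrays, 253 to 324 values per array lie below 1, and the mean after trimming 2% of the probe sets at each end is 500 on every array. That is the form of the MAS5 algorithm, which scales each array by 1 factor. Detection calls, array files, the annotation version and a genome build are not given in the sources used here.

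The table held 45101 probe sets, of which 64 are controls. Outside the controls, 34945 probe sets are paired with exactly 1 gene symbol, 932 with several and 9160 with none; those with several or none were left out. The probe sets with 1 symbol name 18193 genes, and 18032 of these matched the RefSeq table (assembly GRCm38.p6, used for names alone) by gene identifier, with 0 symbols updated. Values were taken to log2. A gene was represented by its probe set of highest mean log2 value over the 4 arrays, and genes whose mean lay below the 25th percentile (5.64) were left out, which left 13645. The array medians were 111, 132, 133 and 137 (WT replicate 1, WT replicate 2, Smad4-KO replicate 1, Smad4-KO replicate 2). The number of arrays limits the precision. The SD of the log2 difference between replicates, over genes in the tenth of lowest signal, was 1.94 in WT and 2.04 in Smad4-KO, and in the tenth of highest signal 0.58 and 0.64.

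The genotypes were compared with limma (version 3.58.1, R 4.3.3), lmFit and eBayes with default settings and genotype as the only term, in a two-sided moderated test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Each standard error and 95% interval of a gene's difference comes from the same fit. The standard error of a list's median does not. It follows the spread among the genes of the list, not the spread between pools. Of the 27 gene lists, the 26 with at least 5 members tested were tested with limma's camera at its preset correlation of 0.01, adjusted over the 26 lists, and again with a correlation estimated from the arrays and with fry. Camera compares a list with the other genes; fry tests whether a list moves, on balance, in 1 direction. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

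The samples' groups, the tests, the 27 lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule names Smad4, the 12 largest rises and the 12 largest falls among genes past the threshold with both Smad4-KO arrays beyond both WT arrays, and up to 4 members of each list past the threshold with the largest differences. Where no member passed, it names the 2 with the lowest unadjusted p, and it names Acta2, Myh11, Tagln, Eln, Mmp12, Ctss and Ccl2 whatever their result. Predicted or unnamed genes are passed over, which applied to 0 of the rises and 1 of the falls.

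The alternatives were a replicate block, quantile normalization, cyclic loess, centring each array on its median, no filter and a filter at the 50th percentile, the mean of a gene's probe sets, every probe set by itself, eBayes with trend and robust, array weights, an adjusted p of 0.10, leaving out each array in turn, and for lists the other set tests and lists without shared members. Leaving out an array leaves its genotype with 1 array, which limma then assumes to vary like the other group. A pair of alternatives was chosen after seeing the data: raising signals below 64 to 64, and a block for the pairs of arrays that match on the labelling controls. A fold written "at least" was computed with signals under 64 raised to 64. It is a lower bound on the measured ratio alone and makes no allowance for the spread between arrays. The lower limit of the interval from the fit lies below it for some genes, such as Arg1, Rtn1, Il6 and Cxcl5. For others, such as Trem2, that limit lies above it. A further 12 gene lists were chosen after seeing the data and are given in the closing section.

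The procedure was tested on simulated data whose gene variances were drawn from the distribution limma fitted to these arrays. Simulated genes were independent of each other, and their spread was the same in both genotypes and unrelated to signal. With 200 of 13645 genes changed, it recovered 0% of the changes of 1, 6% of those of 2, 56% of those of 3 and 86% of those of 4 on the log2 scale, and 8 of its 82 calls were unchanged genes. With 10% of the genes changed it recovered 1.76%, 59.5%, 89.7% and 96.8%, and 34 of 879 calls were unchanged genes. With no gene changed it called 0 genes and 0 lists. Because genes that move together were not simulated, this does not test the list calls against correlation between genes.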

Results

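The series compared aortas of mice that lack Smad4 in smooth muscle cells (Smad4-KO) with aortas of wild-type littermates (WT) at 6 weeks of age. Smad4 is the shared partner of the receptor-activated Smad proteins in TGF-beta and BMP signalling. Each Affymetrix array was hybridised with 400 ng of RNA from a pool of 3 to 5 vessels, and each genotype had 2 arrays, called replicate 1 and replicate 2. The median signals over 45101 probe sets were 111 and 132 on the WT arrays and 133 and 137 on the Smad4-KO arrays. A value written after ± is the standard error of a difference between 2 and 2 arrays from limma. The number of arrays limits the precision of every value.

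The first comparison asks how far the targeted transcript itself differed between the genotypes. Smad4 had 3 probe sets, and its brightest gave signals of 4394 and 3819 in WT and 2676 and 3580 in Smad4-KO. Both Smad4-KO arrays lay below both WT arrays, and the log2 difference was -0.40 ± 0.32 (95% interval -1.21 to 0.40), which did not pass the test (adjusted p = 0.626). A dimmer Smad4 probe set gave 1213 and 1778 in WT and 658 and 942 in Smad4-KO, a log2 difference of -0.90 that did not pass either (adjusted p = 0.562 in a fit of every probe set). The remaining Smad4 probe set gave 4306 and 3550 in WT and 2018 and 4166 in Smad4-KO, so the genotypes overlapped. The labels do not say which part of the gene was deleted, and a probe set outside that part checks nothing. Cells other than smooth muscle in the vessel wall keep an intact gene.

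The second comparison asks which genes differ between aortas with and without Smad4 in their smooth muscle. In the Smad4-KO aortas, contractile genes of smooth muscle were lower, while genes of macrophages, of chemokines, of antigen presentation and of the interferon response were higher. Camera called these lists at its preset correlation but not with an estimated correlation (adjusted p = 0.268 to adjusted p = 0.305), and fry did not call the chemokine (adjusted p = 0.0813) and interferon lists (adjusted p = 0.0857). Cnn1, an actin-binding protein of smooth muscle, fell 5.97-fold (log2 difference -2.58 ± 0.29), and Ptprc, the surface phosphatase of white blood cells, rose 12.7-fold (3.66 ± 0.31). Nerve cell genes were higher too (adjusted p = 0.268 with an estimated correlation): Th, which makes the precursor of noradrenaline, rose 32.7-fold (5.03 ± 0.30). The largest fall was that of Sost, a secreted Wnt inhibitor, at 87.0-fold (-6.44 ± 0.31).

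Of 13645 genes tested, 861 passed an adjusted p of 0.05 in limma, 672 of them higher and 189 lower in Smad4-KO. Of these, 559 rose and 120 fell by at least 2 on the log2 scale, and the median difference of all genes tested was -0.01. Both Smad4-KO arrays lay beyond both WT arrays for 6448 genes, 47.3% of those tested, where chance gives 33.3%. Arrays of a genotype correlated across genes at 0.950 (WT) and 0.898 (Smad4-KO), and arrays of different genotypes at 0.814 to 0.854; genes are not independent replicates. Centring each array on its median moved the median difference of all genes to -0.22. Relative to that shift 453 genes rose and 225 fell, so 66.8% rather than 78.0% of the called genes were higher. With genes below the 50th percentile of signal left out, the split was 480 to 224. Leaving out either WT array lowered the count, with the residual spread then taken from the Smad4-KO pair alone. The replicates of that pair differed more across genes (SD of the log2 difference 0.88, against 0.67 in WT). Without WT replicate 1, 270 genes passed. Without WT replicate 2 limma called 0, with 1791 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0552. WT then had 1 array, and the log2 differences of the 78 named genes past the threshold were 0.712 to 1.29 times those from all arrays. Their direction could not turn, because both Smad4-KO arrays lay beyond both WT arrays for each of them. The count was also 0 when genes of low signal were kept (2788 at an unadjusted p under 0.05) and with a block for the labelling pairs described next (2658 at an unadjusted p under 0.05). In both labelling pairs all 861 genes kept their direction, but they were called from these same arrays, so this is no independent check. Their medians were 2.66 and 2.67 for genes called higher and -2.26 and -2.04 for genes called lower.

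Measures other than genotype also set the arrays apart. The ratio of 3' to 5' signal of the Dap labelling spike was 10.02 on WT replicate 1 and 14.1 on Smad4-KO replicate 2, against 2.96 on WT replicate 2 and 3.62 on Smad4-KO replicate 1, and beta-actin split the arrays in the same way (11.4, 12.8, 4.19 and 2.83 in that order). Xist, the transcript of the inactive X chromosome, had signals of 15192 on WT replicate 1 and 6223 on Smad4-KO replicate 1, but 90.0 on WT replicate 2 and 135 on Smad4-KO replicate 2. The hybridization controls also followed the replicate number: their mean log2 deviations were -0.20 (WT) and -0.30 (Smad4-KO) on the arrays numbered 1, and 0.32 and 0.18 on those numbered 2. The Y-linked genes Uty (0.33 ± 0.57, adjusted p = 0.859) and Kdm5d (0.21 ± 0.42, adjusted p = 0.881) did not pass, and 4 of the 5 sex-linked genes could be tested, with 0 past the threshold in limma, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Their median log2 difference was 0.18. Kdm5d turned negative with median centring, and both turned negative without WT replicate 1 (Kdm5d -0.29, Uty -0.49). Because both splits put an array of each genotype on each side, the values within each pair of arrays are given beside the gene lists.

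**Figure D1:**
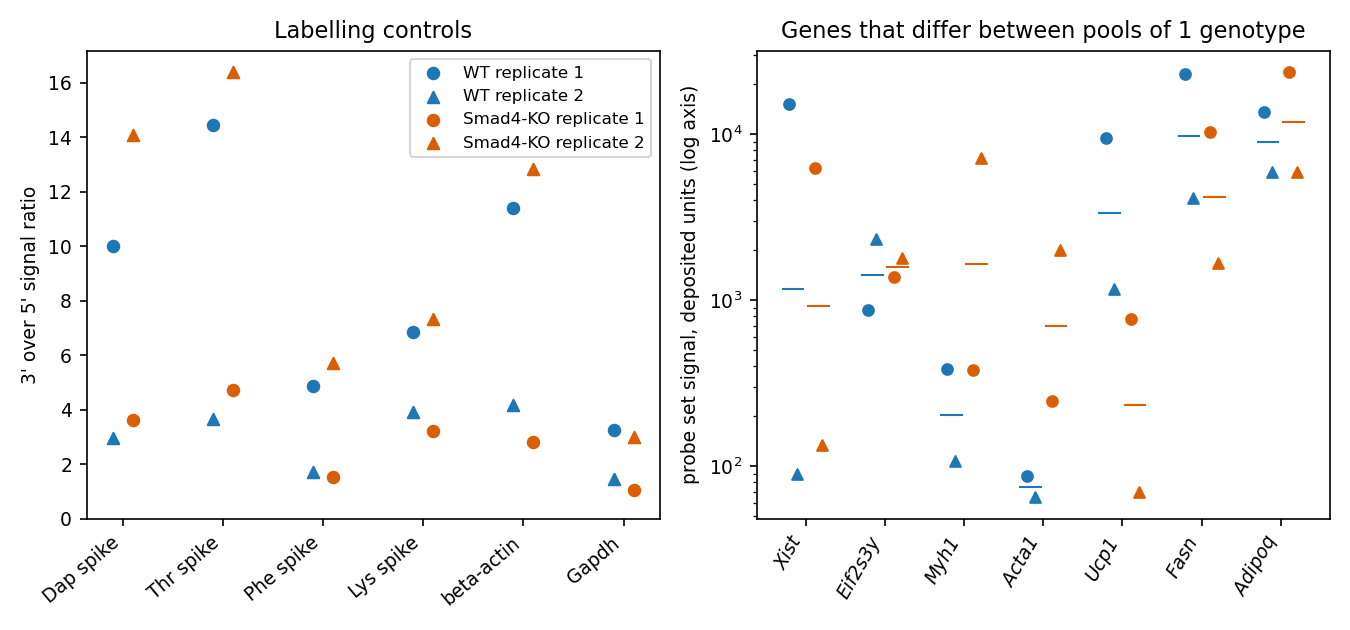
Left, ratio of 3' to 5' signal of 4 labelling spikes and of beta-actin and Gapdh on each array. Right, signal of 7 genes on each array on a log axis, with bars at the geometric mean of each genotype; Xist reads 15192 and 6223 on the arrays numbered 1 and 90.0 and 135 on those numbered 2.

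Among the 12 largest rises, several genes belong to macrophages: Acod1, which makes itaconate (log2 difference 7.25 ± 0.78), Arg1, which splits arginine (6.54 ± 0.69), and Trem2, a lipid receptor of phagocytes (6.54 ± 0.31). Slfn1 (5.98 ± 0.66) and Cyp4f18 (5.95 ± 0.70) rose with them. Others are genes of nerve cells: Snap25, a protein of synaptic vesicle release (5.95 ± 0.45), Scn9a, a sodium channel (5.94 ± 0.85), Amph, a synaptic endocytosis protein (6.06 ± 0.82), Mapk10 (6.29 ± 0.30), Rtn1 (6.38 ± 1.11), and Ret, the receptor of GDNF family ligands (5.83 ± 1.06). The cationic amino acid transporter family member Slc7a14 rose as well (7.78 ± 1.18). In WT, all of these except Snap25 averaged below a signal of 64, where replicate noise was high. Their folds are therefore given as bounds on the measured ratio, without allowance for that noise. Their order by log2 difference is not one of size. With signals under 64 raised to 64, Arg1 was at least 54.5-fold higher, Rtn1 at least 33.3-fold, Mapk10 at least 31.1-fold, Slc7a14 at least 20.2-fold and Trem2 at least 9.16-fold, while Acod1 and Slfn1 no longer passed the test.

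Sost led the 12 largest falls and Casq1, a calcium-binding protein of the sarcoplasmic reticulum, came next at 24.3-fold (-4.60 ± 0.59). Dsp, a desmosome protein, fell 16.1-fold (-4.01 ± 0.29), Lgr6, a receptor of R-spondins, 14.6-fold (-3.87 ± 0.34), and Optc, a small proteoglycan, 14.1-fold (-3.82 ± 0.31). Hhip, which binds hedgehog ligands, fell at least 12.0-fold with signals under 64 raised to 64 (-4.13 ± 0.43). Muscle genes in the group were Mylk4, a kinase of the myosin light chain kinase family, which fell 12.5-fold (-3.64 ± 0.31), Sh3bgr, 11.0-fold (-3.46 ± 0.29, a call that ended with the mean of its probe sets), and Myoz2, a Z-disc protein (-3.77 ± 0.74), which no longer passed with that floor. Col4a6, a basement membrane collagen, fell 11.7-fold (-3.55 ± 0.34), Stum 13.2-fold (-3.72 ± 0.41) and Sh3rf2 at least 7.86-fold (-4.00 ± 0.38). Sost read 13903 in WT and 160 in Smad4-KO as geometric means, and Dsp 10209 and 634.

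**Figure D2:**
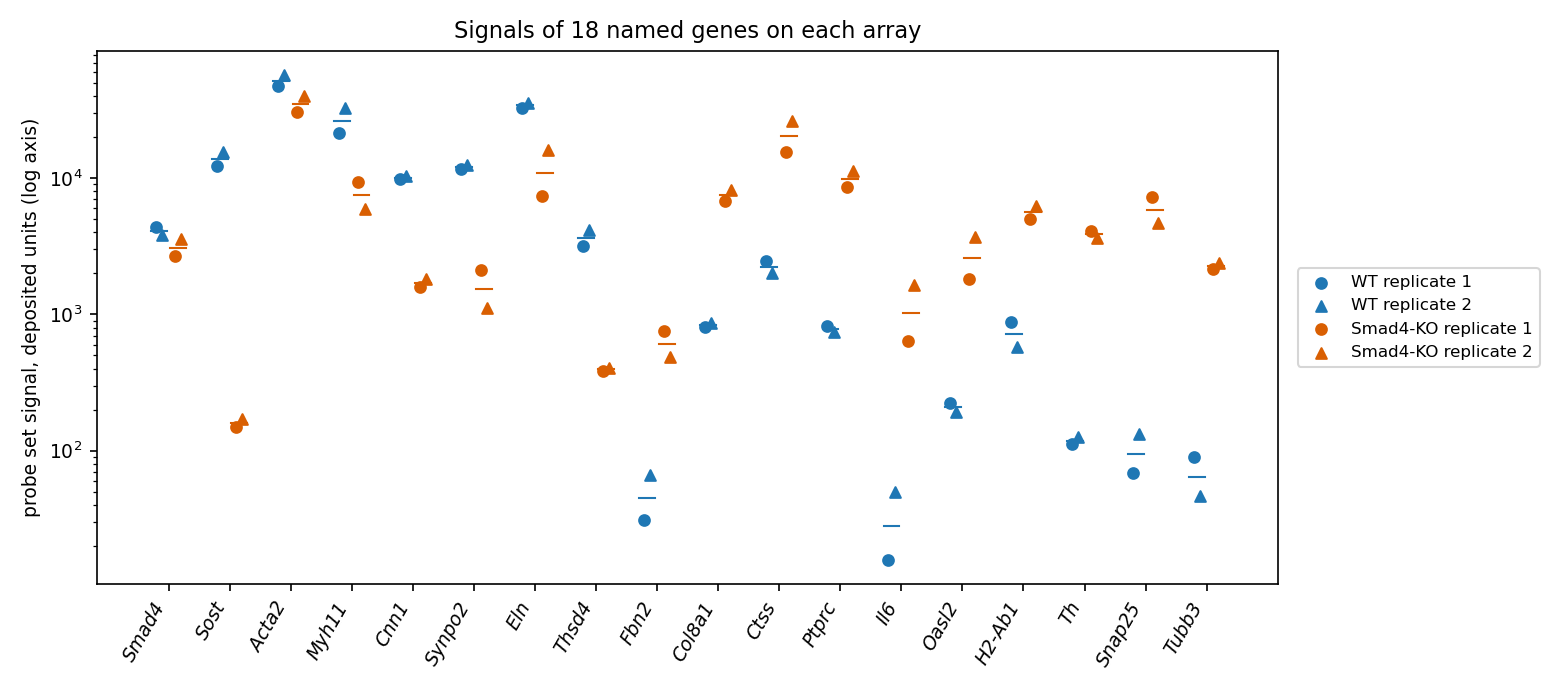
Signal of 18 named genes on each array on a log axis, with bars at the geometric mean of each genotype. Sost averages 13903 in WT and 160 in Smad4-KO, Th averages 118 and 3867, and Acta2 averages 52025 and 35034.

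Of the contractile smooth muscle list, 10 of 27 members fell over all genes tested and 22 fell adjusted over the list alone; all 27 differences were negative. The median log2 difference was -1.52 (camera, adjusted p = 2.3e-17; adjusted p = 0.268 with an estimated correlation), and it lay between -1.40 and -1.78 in the 4 pairs of arrays. Synpo2, an actin-bundling protein, fell 7.81-fold (-2.96 ± 0.40), Lmod1, a nucleator of actin filaments, 5.86-fold (-2.55 ± 0.35), and Ppp1r14a, an inhibitor of myosin phosphatase, 5.66-fold (-2.50 ± 0.39). Abundant structural genes had differences that did not pass: Myh11 -1.82 ± 0.40 (adjusted p = 0.0633), Tagln -1.12 ± 0.31 (adjusted p = 0.116) and Acta2 -0.57 ± 0.32 (adjusted p = 0.447). The Acta2 probe set read 47232 and 57304 in WT, where the highest signals of any probe set were 54742 and 73520. Its difference lay between -1.98 and -0.29 over 16 alternatives and passed under none. Myh11 passed under 5 of 16 alternatives, the replicate block and median centring among them (adjusted p from 0.0355 to 0.301 over all 16). Macrophage markers (median 2.62) and nerve cell markers (median 2.49) were higher in the same arrays.

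Genes of prostaglandin, nitric oxide and calcium signalling in smooth muscle were also called lower as a list, with a median of -0.87 (camera, adjusted p = 0.000239; adjusted p = 0.268 with an estimated correlation) and pair medians between -0.65 and -1.19. Of its 20 members, 1 rose and 1 fell; adjusted over the list alone, 2 rose and 6 fell. Cacnb2, a subunit of voltage-gated calcium channels, fell 3.09-fold (-1.63 ± 0.31, a call that ended with the mean of its probe sets), and Agtr1a, the angiotensin II receptor, rose 6.24-fold (2.64 ± 0.34). With fry, which tests whether a list moves on balance one way, the list was not called (adjusted p = 0.0574). Contractile genes (median -1.52) were lower in the same arrays, and macrophage (2.62) and nerve cell markers (2.49) higher.

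Among genes downstream of BMP receptors, Atoh8, a transcription factor, fell at least 3.76-fold (-2.12 ± 0.33), Smad6, an inhibitor of BMP signalling, 4.08-fold (-2.03 ± 0.36) and Id4 3.58-fold (-1.84 ± 0.29), while Bmper, a secreted BMP-binding protein, rose 5.49-fold (2.46 ± 0.35). Of 13 members of the BMP and Id target list, 3 fell and 1 rose; adjusted over the list alone, 6 fell and 2 rose. The list's median was -0.85 (camera, adjusted p = 0.00211; adjusted p = 0.268 with an estimated correlation), with pair medians between -0.85 and -1.17. In the same arrays the contractile median was -1.52, the macrophage median 2.62 and the nerve cell median 2.49. Of 24 TGF-beta target genes, 2 fell, and 3 fell adjusted over the list alone: Fstl3, a secreted activin antagonist, fell 5.63-fold (-2.49 ± 0.32) and Tgfb1i1, a focal adhesion protein, 2.79-fold (-1.48 ± 0.29). The median of that list was -0.51 (camera, adjusted p = 0.0269; adjusted p = 0.439 with an estimated correlation), with pair medians from -0.69 to -0.10. Of 29 ligands, receptors and Smads of these pathways, 2 fell over all genes and 2 adjusted over the list alone: Bmpr1b, a BMP receptor, fell 7.63-fold (-2.93 ± 0.48) and Ltbp1, which holds latent TGF-beta in the matrix, 3.93-fold (-1.98 ± 0.36). Its median was -0.23 (camera, adjusted p = 0.0269; adjusted p = 0.537 with an estimated correlation), with pair medians from -0.44 to -0.07. The call of the TGF-beta targets was lost under 7 of 19 alternatives (adjusted p from 0.00331 to 0.439), among them quantile normalization (adjusted p = 0.089) and leaving out Smad4-KO replicate 1 (adjusted p = 0.35). That of the ligands and receptors was lost under 8 of 19 (adjusted p from 0.0111 to 0.537), among them quantile normalization (adjusted p = 0.089) and leaving out WT replicate 2 (adjusted p = 0.104) or Smad4-KO replicate 2 (adjusted p = 0.118). Tgfb1i1 and Ltbp1 did not pass after quantile normalization, nor did Tgfb1i1, Smad6, Id4 and Bmpr1b with the mean of a gene's probe sets.

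Genes of the extracellular matrix moved in both directions. Col8a1, a short-chain collagen of vessel walls, rose 8.91-fold (3.16 ± 0.30), Thbs1, a matricellular protein, 7.52-fold (2.91 ± 0.57), Col12a1, 5.16-fold (2.37 ± 0.30), and Col8a2, 5.05-fold (2.34 ± 0.34). Thsd4, which promotes fibrillin microfibrils, fell 9.23-fold (-3.21 ± 0.31), Fbn2, a fibrillin of development, rose at least 9.34-fold (3.75 ± 0.48), and Eln, the elastin gene, had a difference of -1.65 ± 0.45 that did not pass (adjusted p = 0.113). Eln passed with the replicate block and without Smad4-KO replicate 2 (adjusted p from 0.0383 to 0.389 over its 16 alternatives). Of 27 collagens and other matrix proteins, 4 rose and 1 fell, and 5 rose and 2 fell adjusted over the list alone. The list was not called (median 0.09, camera, adjusted p = 0.701), and its direction turned without WT replicate 1 (median -0.12) or Smad4-KO replicate 2 (median -0.32). The fall was that of Col18a1 (-2.09), named after its value was seen. Of 18 elastic fibre genes, 1 rose and 1 fell, and 3 rose and 5 fell adjusted over the list alone (median -0.13, camera, adjusted p = 0.269). Without Smad4-KO replicate 2 this list was called lower (median -0.49, adjusted p = 0.0291, in a range of 0.0291 to 0.808 over its alternatives). The matrix-degrading proteases were called higher, with a median of 0.62 (camera, adjusted p = 1.61e-05; adjusted p = 0.268 with an estimated correlation) and pair medians between 0.67 and 0.76. Of its 28 members, 7 rose and 0 fell, and 11 rose and 1 fell adjusted over the list alone. Adam8 rose 10.2-fold (3.36 ± 0.34), Ctss, a cysteine protease abundant in macrophages, 9.14-fold (3.19 ± 0.38), Adam12 6.14-fold (2.62 ± 0.47) and Mmp13, a collagenase, at least 4.64-fold (4.30 ± 0.52). Mmp12, the macrophage elastase, had a difference of 2.28 ± 0.70 that did not pass (adjusted p = 0.146) but did with the replicate block and without WT replicate 1 (adjusted p from 0.0181 to 0.346 over its 15 alternatives). Adam12, Mmp13 and Thbs1 no longer passed with signals under 64 raised to 64, nor Col12a1, Thbs1 and Adam12 with the mean of probe sets, and macrophage markers were higher in the same arrays (median 2.62).

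Cartilage and bone genes had no common direction: of 16 chondrogenic and osteogenic genes, 1 rose and 2 fell, with 2 and 2 adjusted over the list alone. Col11a1, a fibrillar collagen of cartilage, rose 9.49-fold (3.25 ± 0.34), Cytl1, a cytokine-like protein of cartilage, fell 7.81-fold (-2.97 ± 0.38), and Hapln1, a hyaluronan link protein, fell at least 2.02-fold (-2.32 ± 0.40), a call that the floor of 64 ended. The list was not called (camera, adjusted p = 0.753), and camera gave it a lower direction while its median was 0.01 and its mean 0.03. The phenotype modulation list of smooth muscle was not called either (camera, adjusted p = 0.898); its median of -0.24 and its mean of 0.13 differed in sign. Of its 18 members 1 rose, Lgals3, a galectin abundant in macrophages (2.76 ± 0.51, 6.77-fold), and 2 rose and 1 fell adjusted over the list alone. Its camera direction turned under all 3 scalings tried and without WT replicate 1 (median 0.12) or Smad4-KO replicate 1 (median 0.40), and the Lgals3 call ended with the floor of 64.

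Macrophage markers rose broadly: 17 of 26 rose over all genes and 22 adjusted over the list alone, with 0 falls by either count. The median was 2.62 (camera, adjusted p = 2.3e-14; adjusted p = 0.268 with an estimated correlation), and pair medians lay between 2.12 and 3.20. Fcer1g, the signalling chain of Fc receptors, rose 13.2-fold (3.72 ± 0.49), Fcgr1 13.8-fold (3.79 ± 0.65) and Aif1, a macrophage calcium-binding protein, at least 19.0-fold (4.34 ± 0.76). Of 26 chemokine and leukocyte adhesion genes, 12 rose and 18 rose adjusted over the list alone, with a median of 2.50 (camera, adjusted p = 2.3e-14; adjusted p = 0.305 with an estimated correlation; fry adjusted p = 0.0813) and pair medians between 1.70 and 3.12. The cytokine Il6 rose at least 15.9-fold (5.18 ± 0.71), Il1b at least 17.7-fold (4.45 ± 0.58), and the neutrophil chemokines Cxcl2 and Cxcl5 at least 14.2-fold (4.93 ± 0.71) and 8.59-fold (5.01 ± 0.97). Ccl2, a monocyte chemokine, had a difference of 3.66 ± 0.85 that did not pass (adjusted p = 0.0748) except with the replicate block (adjusted p from 0.0104 to 0.226 over its 15 alternatives). Antigen presentation genes were higher: 8 of 10 members of the MHC class II list rose and 9 adjusted over the list alone, with a median of 2.13 (camera, adjusted p = 1.06e-07; adjusted p = 0.305 with an estimated correlation) and pair medians between 1.83 and 2.75. Its largest rises were Itgax, an integrin of dendritic cells and macrophages, 9.46-fold (3.24 ± 0.37), H2-Ab1 7.86-fold (2.98 ± 0.35), Cd74, the invariant chain, 6.86-fold (2.78 ± 0.45), and H2-Eb1 6.78-fold (2.76 ± 0.39). The calls of Cxcl2, Aif1 and Fcgr1 ended with the floor of 64, and those of Aif1 and Cd74 with median centring. With the mean of a gene's probe sets, Ptprc, Fcgr1 and Cxcl5 did not pass.

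Interferon response genes rose together: 10 of 21 rose, and all 21 adjusted over the list alone. The median was 2.49 (camera, adjusted p = 2.26e-14; adjusted p = 0.305 with an estimated correlation; fry adjusted p = 0.0857), with pair medians of 1.76 and 3.39 in the pairs of equal number. Oasl2 rose 12.4-fold (3.63 ± 0.43), Oas1a 9.21-fold (3.20 ± 0.51) and Oas2 8.42-fold (3.07 ± 0.40), all relatives of the enzyme that senses double-stranded RNA, and Mx1, an antiviral GTPase, rose at least 13.3-fold (4.18 ± 0.75), a call that ended with the floor of 64. Among T and B lymphocyte markers, 1 of 13 rose, and 8 rose and 1 fell adjusted over the list alone. Cd3d, a chain of the T cell receptor complex, rose 5.02-fold (2.33 ± 0.37). Its call ended with median centring. The list's median was 1.66 (camera, adjusted p = 0.000268; adjusted p = 0.397 with an estimated correlation; fry adjusted p = 0.139), with pair medians between 0.83 and 2.84. Of 25 cell cycle genes, 3 rose and 17 rose adjusted over the list alone: Cdk1 rose 3.72-fold (1.90 ± 0.35), Mki67 3.66-fold (1.87 ± 0.37) and Top2a 3.37-fold (1.75 ± 0.30), all calls that ended with median centring or with the mean of a gene's probe sets. The cell cycle list had a median of 1.38 (camera, adjusted p = 5.76e-09, and adjusted p = 0.268 with an estimated correlation) and pair medians between 1.07 and 1.73. Macrophage markers (median 2.62) and nerve cell markers (2.49) were higher in the same arrays as these 3 lists.

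Of 17 Schwann cell and neuronal markers, 10 rose and 12 rose adjusted over the list alone, with 0 falls by either count. Tubb3, the neuronal tubulin, rose at least 29.9-fold (5.14 ± 0.41), and Nefm, a neurofilament, at least 30.3-fold (4.95 ± 0.31). The list's median was 2.49 (camera, adjusted p = 4.7e-11; adjusted p = 0.268 with an estimated correlation), with pair medians between 2.23 and 2.74.

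**Figure D3:**
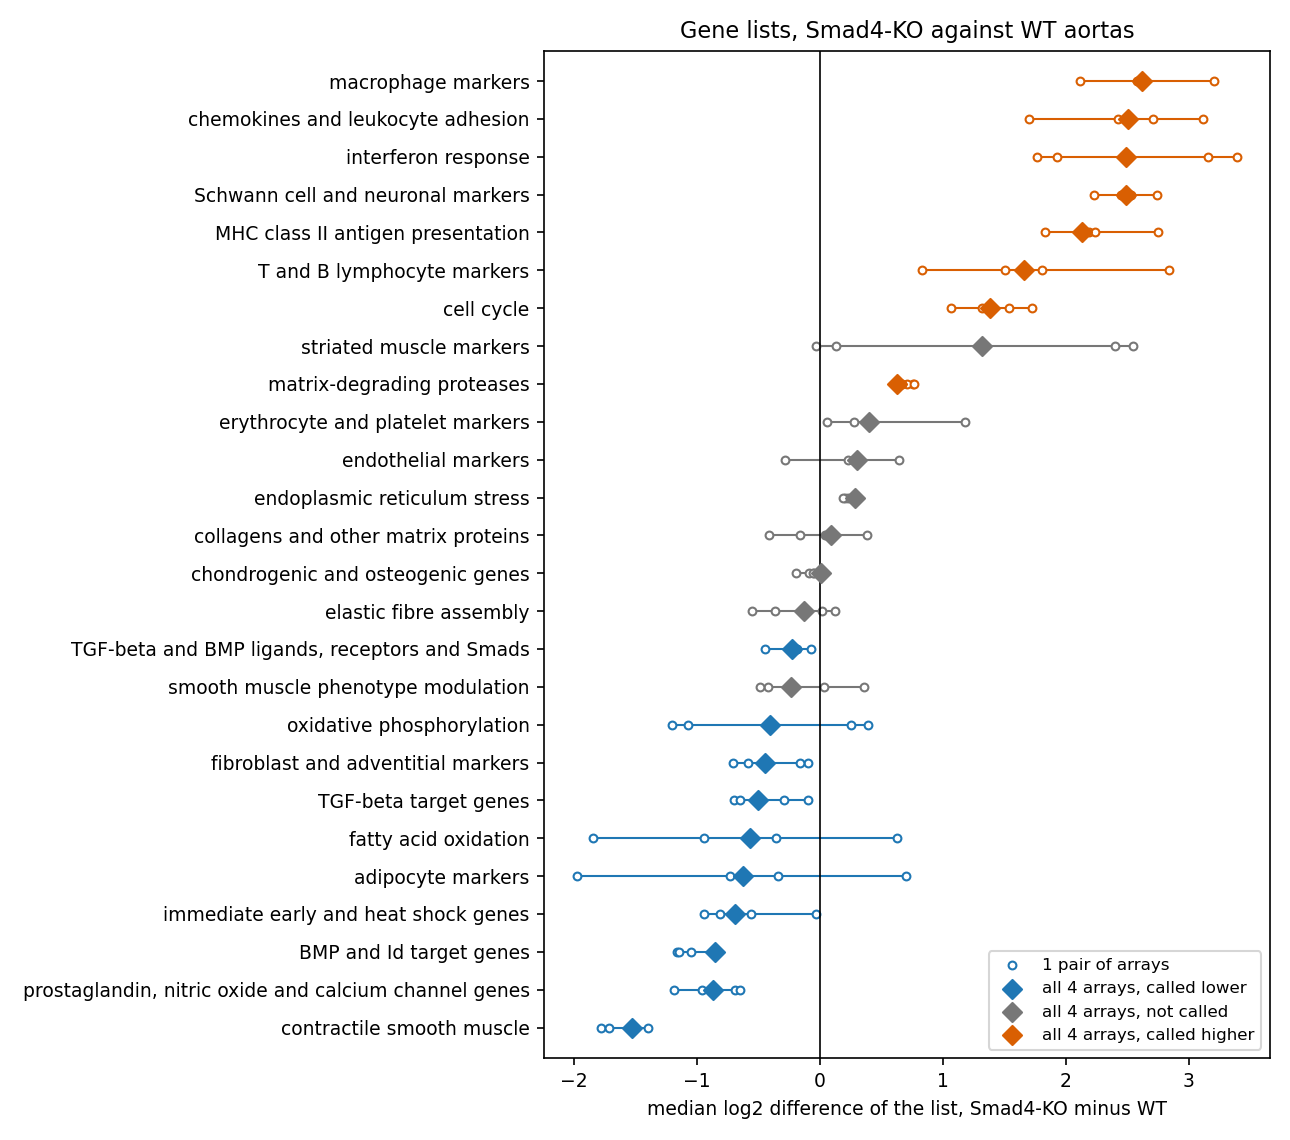
Median log2 difference, Smad4-KO minus WT, of the 26 gene lists tested. Diamonds give the median over all 4 arrays, coloured by the call of camera with its preset correlation, and open circles the medians in the 4 pairs of a Smad4-KO with a WT array; the macrophage median is 2.62 and the contractile median -1.52, while fatty acid oxidation, adipocyte and oxidative phosphorylation medians lie on both sides of 0.

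Markers of endothelial cells and fibroblasts had medians nearer to 0. Of 24 endothelial markers 0 passed in limma (4 at an unadjusted p under 0.05), and 0 adjusted over the list alone (median 0.30, camera, adjusted p = 0.73). The members with the lowest p were Kdr, a VEGF receptor (1.40 ± 0.38, adjusted p = 0.113), and Robo4 (1.14 ± 0.39, adjusted p = 0.186). Its camera direction turned without WT replicate 2 (median 0.01) or Smad4-KO replicate 1 (median 0.06). Of 20 fibroblast and adventitial markers 1 fell, also adjusted over the list alone: Pcolce2, an enhancer of procollagen processing, fell 7.03-fold (-2.81 ± 0.31). The list's median was -0.45 (camera, adjusted p = 0.0112; adjusted p = 0.305 with an estimated correlation), with pair medians from -0.71 to -0.09. This call was lost under 5 of 19 alternatives (adjusted p from 0.00146 to 0.305), among them quantile normalization (adjusted p = 0.089) and leaving out Smad4-KO replicate 1 (adjusted p = 0.151). Of 11 erythrocyte and platelet markers 0 passed in limma (3 at an unadjusted p under 0.05) and 1 rose adjusted over the list alone (median 0.40, camera, adjusted p = 0.31). The platelet chemokines Ppbp (2.40 ± 0.50, adjusted p = 0.0555) and Pf4 (1.34 ± 0.34, adjusted p = 0.0935) came closest. Ppbp passed under 5 of 16 alternatives, the replicate block and leaving out Smad4-KO replicate 2 among them (adjusted p from 0.00655 to 0.248 over all 16). Of 18 striated muscle genes 2 fell, also adjusted over the list alone, Casq1 (above) and Myh6, a cardiac myosin (-2.44 ± 0.38, a call that the floor of 64 ended). The list's median was 1.32 (camera, adjusted p = 0.748). That median followed Smad4-KO replicate 2, on which Myh1, a myosin of fast skeletal muscle named after its values were seen, read 7191 against 382 and 107 in WT and 380 on the other Smad4-KO array. Without Smad4-KO replicate 1 the striated muscle list was called higher (median 2.40, adjusted p = 0.00881, in a range of 0.00881 to 0.996 over its alternatives), and without Smad4-KO replicate 2 its median was -0.01.

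Fat and mitochondrial genes varied between pools of a genotype, and no member of these lists passed in limma. At an unadjusted p under 0.05 there were 2 adipocyte markers, 0 fatty acid oxidation genes and 0 oxidative phosphorylation genes. Adipocyte markers had a median of -0.62 (0 of 20 past the threshold, 0 adjusted over the list alone; camera, adjusted p = 0.0175; adjusted p = 0.725 with an estimated correlation), fatty acid oxidation genes -0.57 (0 of 20, 0 adjusted over the list alone; adjusted p = 0.0112; adjusted p = 0.725 with an estimated correlation), and oxidative phosphorylation genes -0.41 (0 of 26, 0 adjusted over the list alone; adjusted p = 0.0165; adjusted p = 0.725 with an estimated correlation). In the pair of WT replicate 1 with Smad4-KO replicate 2 these medians were -1.97, -1.84 and -1.07, and in that of WT replicate 2 with Smad4-KO replicate 1 they were 0.70, 0.63 and 0.25. Members with the lowest p were Dio2 (-1.92 ± 0.45, adjusted p = 0.0763), Ucp1, the uncoupling protein of brown fat (-3.84 ± 1.42, adjusted p = 0.222), Acadvl (-1.04 ± 0.59, adjusted p = 0.449), Hadhb (-0.69 ± 0.41, adjusted p = 0.478), Uqcrc1 (-0.84 ± 0.50, adjusted p = 0.476) and Cyc1 (-0.72 ± 0.57, adjusted p = 0.629). Dio2 passed under 3 of 16 alternatives (adjusted p from 0.0333 to 0.344) and Ucp1 under 1, the replicate block (adjusted p from 0.000572 to 0.589). Without WT replicate 1 the medians were 0.12, 0.08 and 0.28 and neither fat list was called (adjusted p = 0.654 and 0.97). Without Smad4-KO replicate 2 the adipocyte median was 0.20, and again neither was called (adjusted p = 0.826 and 0.376). Quantile normalization ended all 3 calls (adjusted p = 0.089, 0.0649 and 0.131), and leaving out Smad4-KO replicate 1 ended that of oxidative phosphorylation (adjusted p = 0.0753). Over all their alternatives the adjusted p reached from 1.86e-10 to 0.97.

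Of 22 immediate early and heat shock genes, 1 fell, also adjusted over the list alone: Fosb, a transcription factor, fell at least 3.41-fold (-1.81 ± 0.33), a call that ended with the mean of its probe sets. The list's median was -0.69 (camera, adjusted p = 0.0112; adjusted p = 0.541 with an estimated correlation), with pair medians from -0.94 to -0.03. That call was lost under 4 of 19 alternatives (adjusted p from 0.000569 to 0.541), among them leaving out WT replicate 2 (adjusted p = 0.156) or Smad4-KO replicate 1 (adjusted p = 0.208). Of 20 endoplasmic reticulum stress genes 0 passed in limma (1 at an unadjusted p under 0.05) and 0 adjusted over the list alone (median 0.28, camera, adjusted p = 0.362), with Sdf2l1 (1.39 ± 0.31, adjusted p = 0.067) and Asns (1.41 ± 0.58, adjusted p = 0.27) closest. Sdf2l1 passed under 2 of 16 alternatives (adjusted p from 0.041 to 0.347). In all, camera called 18 of 26 lists, 8 higher and 10 lower. With correlations estimated from the arrays it called 0 of them (lowest adjusted p 0.268, 3 at an unadjusted p under 0.05), and fry called 7.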

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

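The signal floor and the block for labelling pairs were chosen after seeing the data. The 861 genes became 1321 with a replicate block (856 shared), 1403 at an adjusted p under 0.10, 518 with the mean of a gene's probe sets and 205 with every probe set by itself. Replicate deviations of the genotypes correlated at -0.01 across genes. Xist and the hybridization controls split the arrays by number, while the labelling controls paired arrays of unlike number. Such opposed effects can cancel in this correlation, so it does not settle whether the arrays are paired. Limma called 0 without a filter (lowest adjusted p 0.0725; 2788 at an unadjusted p under 0.05; 18193 genes tested) and 0 with the labelling block (lowest 0.0557; 2658 unadjusted; the cause was not tested). Leaving out 1 array gave 0 (without WT replicate 2) to 808. Under the other 7 alternatives the count was 678 to 1004. The Smad4 difference did not pass under any of its 16 alternatives (-0.62 to -0.19).

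Of 18 lists called, 0 were called with an estimated correlation and 7 with fry; the replicate block, the labelling block, camera on ranks and lists without shared members kept every list's call.

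Directions turned as follows, and the cause was not tested. Of these, oxidative phosphorylation, adipocyte markers and fatty acid oxidation had been called in the first fit. Kdm5d was -0.0051 with median centring, -1.30 with the mean of probe sets and -0.29 to 0.71 leaving out 1 array, Uty then -0.49 to 1.14 and Cyc1 -1.52 to 0.085. Phenotype modulation medians were -0.11 (quantile), -0.054 (loess), -0.45 (centring), -0.24 (fry, of opposite sign) and -0.43 to 0.40 leaving out 1 array; striated muscle 0.84 (no filter), 1.32 (fry) and -0.0095 to 2.40; chondrogenic 0.11 (no filter), -0.11 (50th percentile), 0.0076 (mean of probe sets) and 0.0076 (fry). Leaving out 1 array gave collagens -0.32 to 0.22, oxidative phosphorylation -1.15 to 0.28, adipocyte markers -1.21 to 0.20, fatty acid oxidation -1.24 to 0.084 and endothelial markers 0.011 to 0.48.

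Of 78 named genes past the threshold, 78 did not pass without a filter, with the labelling block or without WT replicate 2, 56 with every probe set by itself, 44 without WT replicate 1, 20 with the mean of probe sets, 18 without Smad4-KO replicate 2, 16 without Smad4-KO replicate 1, 14 with the floor of 64, 10 with median centring, and 1 to 4 under the quantile, loess, array weight, trend and replicate block alternatives. Named genes that had not passed did so under some: 7 with the replicate block (Myh11, Eln, Mmp12, Ccl2, Ppbp, Dio2, Ucp1), 4 each with trend and the 50th percentile filter, 2 without Smad4-KO replicate 2, and 1 each with loess, median centring, the mean of probe sets and without WT replicate 1. Dim signals limit what can be called: near a mean signal of 101 WT replicates differed with an SD of 0.87, near 4924 with 0.58. Near 6.85 the SD was 1.94, but the main fit left out genes that dim.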

Other observations

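The 12 gene lists of this part were chosen after seeing the data, and the tests of blood, of the smooth muscle share, of labelling, of sex composition and of other splits of the arrays after their result was seen.

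Neutrophil genes were higher in Smad4-KO aortas: 12 of 16 rose over all genes and 16 adjusted over the list alone, with a median log2 difference of 3.71 (camera, adjusted p = 8.61e-14, and adjusted p = 0.107 with an estimated correlation). Macrophage markers were higher in the same arrays (median 2.62, 17 of 26 rose). Clec4d, a lectin of myeloid cells, rose by 5.73, S100a9, a calcium-binding protein of neutrophil cytosol, by 4.70 and Csf3r, the receptor of G-CSF, by 4.46; 2 members of the list stand on the first lists too. Basement membrane genes were lower: 6 of 20 fell, and 8 fell and 1 rose adjusted over the list alone (median -0.92, camera, adjusted p = 4.92e-06; adjusted p = 0.187 with an estimated correlation). Besides Col4a6, Npnt, an integrin ligand, had a difference of -3.31, Col4a4 -2.98 and Col4a3 -2.48; 5 members stand on the first lists. Genes of the sarcoplasmic reticulum and Z-disc, beside a contractile median of -1.52 and a striated muscle median of 1.32, fell in 11 of 21 cases over all genes and 13 adjusted over the list alone (median -2.32, camera, adjusted p = 1.94e-09; adjusted p = 0.107 with an estimated correlation). Asb2, a ubiquitin ligase subunit of muscle, had a difference of -3.35, Tcap, a titin-binding protein, -3.15 and Jph2, which links surface membrane and reticulum, -2.60; 2 members stand on the first lists. This list was made after the largest falls were seen and holds 4 of them (Casq1, Sh3bgr, Mylk4 and Myoz2), so its count and test partly restate that choice; without them 7 of 17 fell, with a median of -1.02 (camera, adjusted p = 7.32e-06; adjusted p = 0.117 with an estimated correlation). The basement membrane list holds 1 of them, Col4a6, without which its median was -0.81.

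A list of semaphorins, netrins and neurotrophins, which also holds slits, an ephrin and endothelins, was lower (median -0.66). Of its 15 members, 2 fell, Nrtn (-1.56) and Ntn1 (-1.52), and 3 fell adjusted over the list alone. In sign 11 differences were negative and 4 positive, Slit2 (1.19) among the latter. Camera called the list (adjusted p = 0.00167) but not with an estimated correlation (adjusted p = 0.2). Wnt inhibitors and receptors went both ways: Sfrp5 rose (2.15) while Sost and Lgr6 fell, and 8 rose and 6 fell adjusted over the list alone, so that the median was 0.04 and the mean -0.35 (camera, adjusted p = 0.955; fry adjusted p = 0.0066). Sost and Lgr6 are among the largest falls, seen before this list was made, and without them its median was 0.26. Of 16 glycolysis genes 2 rose, Aldoc (2.89) and Eno2 (2.37), both abundant in nerve cells. Of 10 mast cell genes 2 rose, Hdc, which makes histamine (2.87, at least 6.34-fold), and Slc18a2, a monoamine transporter that nerve cells carry too (5.19). Neither list was called (medians 0.17 and 0.29, adjusted p = 0.388 and 0.378).

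Nerve cell genes were higher in both Smad4-KO pools, with a median of 2.49 over 17 markers. The labels name aortas, beside which sympathetic ganglia and the adrenal glands lie. Genes of sympathetic nerve cell bodies, 0 of which stand on the first lists, had a median of 1.80 over 13 genes. Fry called that list (adjusted p = 0.0066), and camera with an estimated correlation did not (adjusted p = 0.107). Over all genes 7 rose, among them Chrnb4 (3.38, at least 6.15-fold), Tfap2b (3.13, at least 6.79-fold) and Isl1 (2.74). The other 6 did not pass, among them Gata3 at 1.75, Hand1 at 0.63 and Eya2 at 0.28. Ganglion glia genes had a median of 1.64 over 11 (5 of them on the first lists), though Sox10 was at -0.74. With an estimated correlation camera did not call them either (adjusted p = 0.117). Ganglion tissue carried into the pools is therefore a candidate source. Adrenal tissue cannot be told apart, since its 6 genes went both ways, Star at 1.74 and Pnmt at -0.23. The median of these genes was 0.55, with a standard error over genes of 0.55. Whether the genotype itself changed the nerves around the vessel was not tested.

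Macrophage and inflammatory genes were higher in both Smad4-KO pools, with a macrophage median of 2.62. Blood left in the vessels would raise haemoglobin and erythroid genes. Their median over 7 genes (6 of them on the first lists) was -0.44, with a standard error over genes of 0.23. Of 13 such genes chosen, these 7 could be tested, and they cover red cells alone. Neutrophil genes were higher (median 3.71). The platelet chemokines Ppbp (2.40) and Pf4 (1.34) had rises that did not pass, on an erythrocyte and platelet list with a median of 0.40. White cells and platelets left from blood were therefore not tested. Lymph node genes had a median of 1.24 with a standard error over genes of 0.70, below the macrophage median. Glycam1, a gene of lymph node vessels, read 4135 on Smad4-KO replicate 1 and 25.4 on replicate 2, and the spread keeps lymph node tissue open for part of the signal. Whether inflammatory cells entered or were activated in the wall itself was not tested.

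Contractile smooth muscle genes were lower in both Smad4-KO pools, with a median of -1.52. A lower share of smooth muscle cells alone would raise the markers of every other cell type alike, but the macrophage and fibroblast medians lay 3.07 apart, with endothelial markers between them. That argues only against a change in which the other cell types keep their proportions. Smooth muscle RNA diluted by added macrophage or nerve tissue would also set these medians apart, so it stays open. Unequal labelling of the arrays is argued against by the pairs matched on the labelling controls, of which the smaller difference was -1.40, and unequal sex composition by the pairs matched on Xist, of which the smaller was -1.52. Expression of these genes per smooth muscle cell was not measured.

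The 4 arrays have 3 splits into 2 and 2, too few for a share under 0.05. The split by genotype called 861 genes, and the highest of the others called 0 in limma. At an unadjusted p under 0.05 in limma there were 256 genes for the split by replicate number and 328 for that by labelling controls. In those splits the difference between genotypes counts as residual spread, which lowers their counts, so they give no baseline for the 861.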
